A study of Mus musculus with 12 samples.

How the data were processed

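Gene expression was measured by RNA sequencing in primary microglia of wild-type C57BL/6 mice. The cells came from the brains of newborn pups and were shaken off mixed glial cultures. They were plated at 50000 cells per well with 2.5 ng of CSF1, a growth factor that microglia need, and were treated for 24 h with vehicle, with 5 µg of full-length neurofilament light chain (NfL) or with 5 µg of the coiled-coil part of NfL. Each of the 3 groups had 4 libraries, numbered 1 to 4, and the labels put each number in a batch of its own (b1 to b4), so that each of the 4 batches held 3 libraries, 1 of each group. Libraries were made with a stranded kit for polyadenylated RNA and sequenced as single reads of 50 bases. Nothing in the labels says whether the batches were separate cultures or separate litters, so the p-values measure the spread between these samples.

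The file deposited by the authors holds raw read counts per Ensembl mouse gene for the 12 libraries, with no normalization. Per the labels, the submitters aligned the reads to GRCm38 with GSNAP. The version of the aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here. The values were whole numbers with a different total in each library. The file listed 52636 gene identifiers, of which 99.6% had a symbol in the GENCODE M21 annotation of GRCm38; identifiers without a symbol held 0.0197% of the counts. Symbols, gene types and coordinates come from that annotation, whose release may differ from the one used for counting. Total counts ran from 20162427 to 31048044 per library. Some genes with many processed pseudogenes had very low counts. Gapdh averaged 0.043 CPM (read counts scaled by the total of the library), Rpl13 0.41 and Tpt1 1.74, whereas Eef1a1 averaged 477 and Actb 2360. All ribosomal protein genes together held 0.345% to 0.396% of the counts of a library. Levels of such genes, and of members of closely related families, are therefore uncertain here.

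Genes were kept with edgeR's filterByExpr (R 4.3.3, edgeR 4.0.16), which left 14687 genes with 99.9% of the counts and removed 37949. Libraries were scaled with TMM factors. All 12 libraries were fitted in 1 quasi-likelihood model with 3 groups and 9 residual degrees of freedom, and each pair of groups was compared with the two-sided edgeR quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Levels are given as the mean and SD of TMM-scaled CPM over 4 libraries, and changes as log2 fold changes with a standard error (SE) taken from the F statistic. Where a 95% interval is given for a change, it is the change plus or minus the t quantile for 9 degrees of freedom times that SE.

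The batch label makes the replicate numbers pair the samples. Across genes, after the mean of each group was removed, libraries with the same number correlated at 0.31 to 0.73 (12 of 12 pairs over 0.1). Libraries with different numbers correlated at −0.46 to 0.44. By the mean correlation with each number, 11 of the 12 libraries correlated best with their own number. Full-length replicate 4 and vehicle replicate 2 correlated more with each other (0.44) than with any library of their own number. The model without the batch was chosen as the main one before the data were examined, and the model with the replicate number as a block (6 residual degrees of freedom) as its alternative.

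Before the data were examined, 29 gene lists were also fixed, 22 of functions and 7 of markers of other cell types. The 28 lists with at least 3 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01. Camera compares the genes of a list with all other genes. Its p-values were adjusted over the 28 lists of each comparison. Alternatives were camera with a correlation estimated from each list, and fry, which asks whether the genes of a list move one way on balance. For each list, called genes were counted after adjustment over all genes and also adjusted over the list alone. Many lists share members: 15 of the 26 genes of disease-associated microglia are in another list.

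The genes named were chosen by a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls against vehicle (5 and 5 between the NfL forms) among called genes with a mean of at least 5 CPM and the same direction in all 4 batches, without predicted genes. From each list in each comparison against vehicle it takes up to 4 called members with the smallest p in the main direction and 1 in the other direction, or the member with the smallest p where none was called. It adds 12 genes whatever their result: Nefl, Tnf, Il1b, Il6, Nos2, P2ry12, Tmem119, Trem2, Apoe, Cd14, Tlr2 and Tlr4. A few genes that the rule names are not reported here. Principal components were computed from log2 CPM of the 1000 most variable genes.

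Alternatives fixed in advance were DESeq2 size factors and upper-quartile factors in edgeR, no filter and a stricter filter on low counts, DESeq2 (1.42.0) and limma-voom in place of the main test, the replicate block with edgeR and with DESeq2, fits of only the groups compared, an adjusted p of 0.01, a log2 fold change of at least 1, and leaving out each library, or each batch with the block. Chosen after the data were seen were leaving out batch 1 without a block, leaving out coiled-coil replicate 1 with the block, summing batches 2 and 4 within each group, comparing the forms in separate batches, and removing a trend with GC content and gene length from each library.

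The main test and the block were also tested on simulated data with the same design. Of 50 genes changed 2-fold in the full-length group the main test called 42%, and of 50 changed 4-fold it called 92%; with the block these shares were 78% and 96%. For the coiled-coil group they were 54% and 84%, and 74% and 94% with the block. Other genes called by mistake numbered 4 and 1 without the block and 10 and 7 with it, of 14460 and 14472 genes. Camera called a list of 20 genes shifted 1.5-fold (adjusted p = 4.2e-23) and none of 28 random lists. The simulated genes varied independently of each other. This check therefore cannot show how the preset correlation serves lists whose genes move together. All 12 columns of the file were used.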

Results

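Gene expression was measured in 12 RNA libraries of cultured mouse microglia, the resident immune cells of the brain, 24 h after the cells met vehicle, full-length NfL or coiled-coil NfL (n = 4 each). NfL is a structural protein of axons that is released into tissue fluid when neurons are damaged. The full-length form carries the head, rod and tail of the protein, and the coiled-coil form its central rod. Each of the 4 batches held 1 library of each group. The total counts of replicates 1 to 4 were 22796052, 22595657, 26129375 and 21370879 with vehicle. They were 29513940, 25903731, 25053069 and 21421782 with full-length NfL, and 26062089, 31048044, 20162427 and 25631511 with coiled-coil NfL. Lyz2, the lysozyme gene of myeloid cells, was the gene with the most counts in every library and took 2.55% to 6.17% of them. Mitochondrial genes, those of the mitochondrial genome, held 0.210% to 0.518%, with all 4 full-length libraries below the vehicle library of the same batch. Nefl, the gene of NfL itself, had 0 to 5 counts per library and Il6 had 0 to 18, too few for a test.

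Batch and treatment both separated the libraries. The first principal component held 51.9% of the variance of the 1000 most variable genes, of which batch accounted for 66.3% and treatment for 30.9%. The second component held 24.9%, with 49.1% by batch and 46.1% by treatment. The share of the first component ran from 37.3% to 58.4% on leaving out single libraries.

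**Figure D1:**
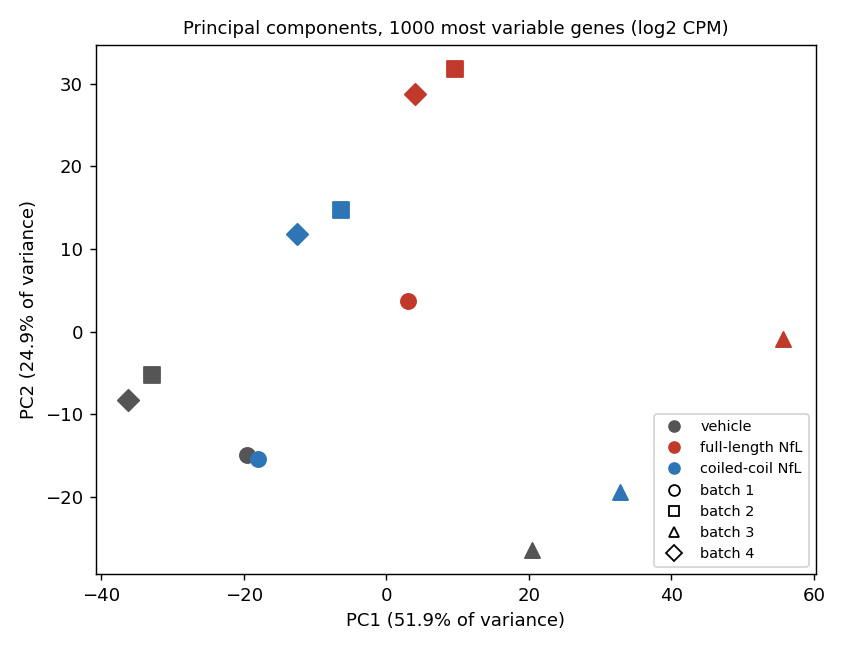
The 12 libraries on the first and second principal components of log2 CPM of the 1000 most variable genes, in percent of variance (51.9% and 24.9%), with colour for treatment and symbol for batch. In each batch the full-length library lies right of and above the vehicle library, the coiled-coil library lies between them in batches 2 to 4, and in batch 1 it lies beside vehicle.

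The first comparison asked what exogenous full-length NfL does to gene expression in microglia. Full-length NfL changed 3656 of 14687 genes, or 24.9% of those tested, with 2062 higher and 1594 lower. Ccl5, Cxcl9, Nos2 and Il1b were among the genes that rose, and Gpr34, Slco2b1, Trem2, Apoe and Igf1 among those that fell. The smallest adjusted p was 0.000265, and a change of at least 2-fold was measured for 308 higher and 435 lower genes. With the replicate number as a block the counts were 3148 and 3284. With batches 2 and 4 summed within each group they were 616 and 424, from 3 libraries per group in a fit chosen after the data were seen. The higher genes were 56.4% of the calls with TMM scaling, 45.8% with upper-quartile scaling and 70.1% once a trend with GC content and gene length was removed, a change chosen after the data were seen. Leaving out single libraries gave 1392 to 2349 higher and 992 to 1735 lower genes, with the fewest lower genes without full-length replicate 2 (992), vehicle replicate 4 (998) and full-length replicate 4 (1013).

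The largest rise among called genes of at least 5 CPM with the same direction in all 4 batches, predicted genes aside, was in Cd300e (ENSMUSG00000048498, GRCm38 chromosome 11, 115051917 to 115062177), an activating receptor of myeloid cells. It went from 0.559 ± 0.337 CPM (SD, n = 4) to 21 ± 7.82, a log2 fold change of 5.22 ± 0.62 (SE; adjusted p = 0.000462). Cxcl9, a chemokine induced by interferons, rose by 4.83 ± 0.83 (adjusted p = 0.00238). Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), a chemokine that attracts T cells and monocytes, went from 26.6 ± 16.3 to 745 ± 344 CPM, a log2 rise of 4.81 ± 0.68 (adjusted p = 0.00102). Slc13a3 (ENSMUSG00000018459, chromosome 2, 165405028 to 165473230), a transporter of dicarboxylates, went from 111 to 2654 CPM, and its vehicle mean was raised by vehicle replicate 1 at 358 CPM. The inhibitory sialic acid receptor Siglece (ENSMUSG00000030474, chromosome 7, 43651070 to 43660161) went from 9.21 to 162 CPM, a log2 rise of 4.14 ± 0.49. Slamf9 rose by 3.96 ± 0.61 and Ccl7 by 3.80 ± 0.90. The class I gene H2-Q6 rose by 3.87 ± 1.01, though short reads can match close relatives such as H2-Q7 as well.

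Slco2b1 (ENSMUSG00000030737, chromosome 7, 99657804 to 99711340), an organic anion transporter of microglia, had the largest fall among called genes of at least 5 CPM with the same direction in all 4 batches, predicted genes aside. It went from 51.6 ± 29.6 CPM in vehicle to 2.63 ± 0.79 with full-length NfL, a log2 fold change of −4.30 ± 0.45 (adjusted p = 0.000386). Dkk2 (ENSMUSG00000028031, chromosome 3, 132085292 to 132180304), a secreted modulator of Wnt signalling, went from 43.7 to 3.41 CPM (−3.66 ± 0.51). Gpr34 (ENSMUSG00000040229, chromosome X, 13632089 to 13640858), a lysophospholipid receptor of microglia, went from 43.3 to 4.37 CPM (−3.31 ± 0.53, adjusted p = 0.00165). Samd4 fell (log2 fold change −3.36), as did the transglutaminase gene F13a1 (−3.05), Asb10 (−2.79) and Cytip (−2.69). Mamdc2 had a change of −3.15 ± 0.88 (adjusted p = 0.0222) that was no longer called without vehicle replicate 4 or full-length replicate 2, 3 or 4 (−2.87 to −3.06).

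**Figure D2:**
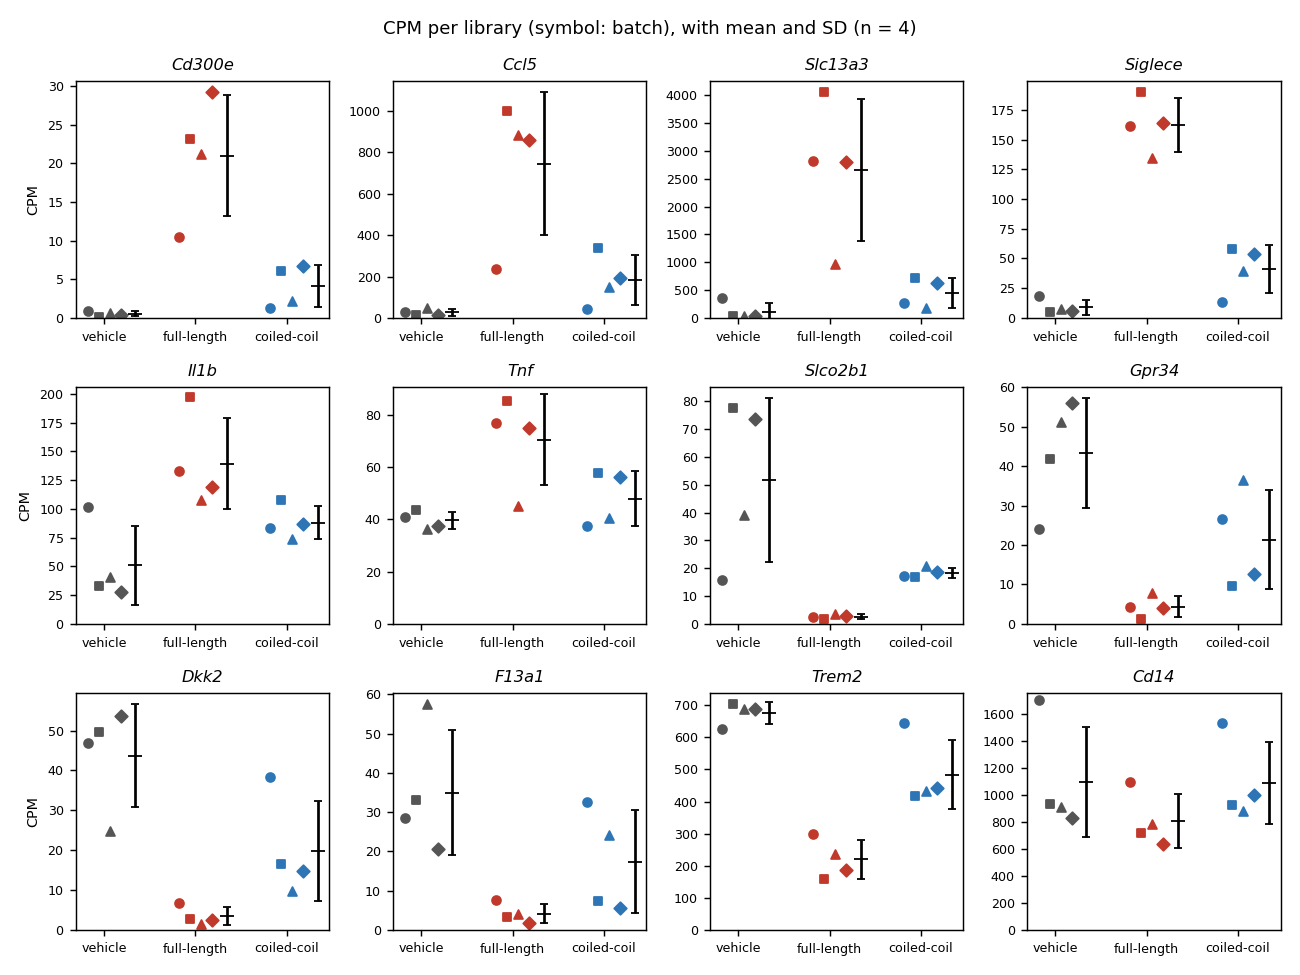
CPM of 12 genes in each library by treatment, with the mean and SD of 4 libraries per group. Ccl5 averaged 26.6 CPM in vehicle, 182 with coiled-coil NfL and 745 with full-length NfL, and Trem2 averaged 677, 484 and 220 CPM.

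Cytokine and inflammatory mediator genes rose as a group with full-length NfL. Of 18 tested, 10 were higher and none lower (11 and 1 adjusted over the list alone, 15 and 1 with the block), and the median log2 fold change was 1.44. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose from 1.27 to 10.4 CPM (3.02 ± 0.43, adjusted p = 0.00101). Il1b rose from 51.0 to 139 CPM (1.45 ± 0.36) and Tnf from 39.6 to 70.5 CPM (0.83 ± 0.19, adjusted p = 0.00889). Acod1, which makes itaconate, rose by 2.26, Ebi3 by 1.64 and the anti-inflammatory cytokine Il10 by 1.92. Camera placed the list above all other genes (adjusted p = 8.65e-06), but not with an estimated correlation (adjusted p = 0.32 with an estimated correlation).

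Among 22 genes of the NF-kB pathway 10 were higher and none lower (12 and 2 adjusted over the list alone; camera adjusted p = 0.00135, and 0.69 with an estimated correlation; 13 and 3 genes with the block). Nfkbiz rose by 1.56 ± 0.23, Traf1 by 2.19 ± 0.35, Ikbke by 1.25 ± 0.26 and the feedback inhibitor Tnip3 by 0.57 ± 0.09. Chemokines split by gene: 6 of 20 rose and 2 fell (8 and 2 adjusted over the list alone, 10 and 2 with the block), with Cxcl13 up by 3.21 ± 0.63 and Ccl24 down (−2.57 ± 0.57). The chemokine list was not called by camera (adjusted p = 0.0729) but was with the block (0.0476, and 0.51 with the block and an estimated correlation), without vehicle replicate 3 (0.0223) and without full-length replicate 4 (0.0441). Of 22 toll-like receptors and adaptors 7 rose and 2 fell (8 and 3 adjusted over the list alone, 9 and 6 with the block; camera adjusted p = 0.287). Tlr1 rose by 1.46 ± 0.19, Irak3 by 1.70 ± 0.23, Ticam2 by 0.69 and Tlr6 by 0.35, and Traf6 fell by 0.35. Of the receptors for bacterial products, Tlr2 and Tlr4 were at like levels in both groups. Tlr2 averaged 411 and 403 CPM (log2 fold change −0.03 ± 0.17) and Tlr4 236 and 212 CPM (−0.15 ± 0.09). Their co-receptor Cd14 had a change of −0.44 ± 0.26 that was called only with the block (adjusted p = 0.228, and 0.00412 with the block).

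Type I interferon genes were higher in 10 of 34 cases and lower in none (15 and 0 adjusted over the list alone), and with the block in 29. Irf7, the interferon-induced regulator of the pathway, rose from 447 to 1735 CPM (1.96 ± 0.50, adjusted p = 0.0149). Bst2 had a rise of 1.07 that was no longer called without vehicle replicate 1 or 4 (0.95 and 0.95). Camera called the list (adjusted p = 7.17e-06, and 0.70 with an estimated correlation). Antigen presentation genes were higher in 10 of 23 cases (13 higher and 2 lower adjusted over the list alone; 15 and 4 with the block). H2-K1 rose by 1.17 ± 0.25 to 2053 CPM and the immunoproteasome gene Psmb8 by 1.10 ± 0.26. Camera called this list as well (adjusted p = 0.0182, and 0.70 with an estimated correlation), but not without vehicle replicate 2 (0.0794), vehicle replicate 4 (0.145) or full-length replicate 3 (0.109), nor with the GC and length trend removed (0.097). Complement genes moved both ways, with 5 of 17 higher and 2 lower (the same counts adjusted over the list alone; camera adjusted p = 0.143, and 0.0344 without vehicle replicate 3; 9 and 3 with the block). Cd55 rose from 0.364 to 6.97 CPM, Cfb by 3.09 ± 0.54, C3 by 1.88 ± 0.42 to 2418 CPM and C2 by 0.76 ± 0.15. Of 15 inflammasome genes 3 rose and 3 fell (3 and 4 adjusted over the list alone, 4 and 6 with the block; camera adjusted p = 0.579), with Gsdmd up by 0.56 ± 0.14.

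Of 26 genes of the disease-associated state, which microglia enter around damaged tissue, 13 fell and 4 rose, over all genes and adjusted over the list alone (median −0.44; camera adjusted p = 0.000219, and 0.32 with an estimated correlation). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), the lipid receptor of that state, fell from 677 ± 34.5 to 220 ± 61.1 CPM (−1.62 ± 0.19, adjusted p = 0.000453). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) fell from 16602 to 8434 CPM (−0.98 ± 0.15, adjusted p = 0.00123). Ank fell by 1.36 and the growth factor gene Igf1 by 1.04 ± 0.15 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042). Fth1, the ferritin heavy chain gene, was measured 1.33 ± 0.23 higher, with the caution that it has many pseudogenes. Of the 22 homeostatic genes 9 fell and 1 rose, over all genes and adjusted over the list alone (median −0.44; camera adjusted p = 0.00612, and 0.32 with an estimated correlation; 13 and 3 with the block). Tgfbr1, the receptor for TGF-beta, fell by 0.79 ± 0.09 and the transcription factor gene Mef2c by 0.91 ± 0.14, while Bin1 rose by 0.56 ± 0.09. P2ry12 averaged 41.8 CPM in vehicle and 37.6 with full-length NfL (−0.16 ± 0.29). Tmem119 differed by 0.72 ± 0.32 (adjusted p = 0.115) and was called with the block (0.00914) and without vehicle replicate 1 (1.15).

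Growth factor genes fell in 8 of 16 cases and rose in none, over all genes and adjusted over the list alone (median −0.63; camera adjusted p = 0.000761, and 0.32 with an estimated correlation). Pdgfb fell by 1.63 ± 0.18, Pros1 by 1.10 ± 0.23 and Vegfb by 0.79 ± 0.13. Of 26 phagocytic and scavenger receptors 10 fell and 4 rose (10 and 6 adjusted over the list alone, 11 and 8 with the block; camera adjusted p = 0.318). Their median was −0.37 and their mean −0.004. Fcgr3 fell by 1.32 ± 0.30 and Scarb2 by 0.56 ± 0.08, whereas Fcer1g, the signalling chain of Fc receptors, rose by 0.91 ± 0.14. Of 30 lysosomal genes 5 fell and 4 rose (5 and 5 adjusted over the list alone, 9 and 7 with the block; camera adjusted p = 0.608). Hexa fell by 0.51 and Ctsd by 0.46. Of 22 matrix genes 4 fell and 1 rose, over all genes and adjusted over the list alone (9 and 4 with the block; camera adjusted p = 0.305), with Plau down by 1.22 ± 0.13, Adamts1 by 1.30 ± 0.24 and the gelatinase gene Mmp9 up by 2.09 ± 0.47. Of 13 alternative activation genes 3 fell and 2 rose, over all genes and adjusted over the list alone (7 and 3 with the block; camera adjusted p = 0.287), and Tgm2 rose by 1.07 ± 0.20. Cholesterol efflux genes had 2 falls and 1 rise among 15, over all genes and adjusted over the list alone (5 and 6 with the block; camera adjusted p = 0.956). Arl4c fell by 0.85 ± 0.10 and Nr1h3, which encodes the receptor LXR-alpha, rose by 1.66 ± 0.33. The median of that list was 0.05, its direction was up in camera and down in fry.

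Of 34 oxidative phosphorylation genes 21 were higher and none lower (25 and 0 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 7.76e-09, and 0.46 with an estimated correlation). The share of counts in genes of the mitochondrial genome went the other way. From vehicle to full-length NfL it was 0.419% to 0.342%, 0.400% to 0.210%, 0.410% to 0.372% and 0.518% to 0.299% in batches 1 to 4. These shares were small, and their difference was not tested. Atp5o rose by 0.78 ± 0.11, Sdhb by 0.74 ± 0.11, Atp5b by 0.51 ± 0.08 and Ndufv2 by 0.47 ± 0.07. Of 18 glycolysis genes 10 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.000115, and 0.32 with an estimated correlation). Hk3 rose by 0.79 ± 0.10 and Hk2 by 0.68 ± 0.10, and Ldha and Tpi1, which have many pseudogenes, by 0.58 and 0.57. Of 23 NRF2 targets 13 rose and none fell, over all genes and adjusted over the list alone (camera adjusted p = 0.000121, and 0.69 with an estimated correlation), with Prdx1 up by 0.73 ± 0.13, Txn1 by 0.81 ± 0.15 and G6pdx by 0.37 ± 0.07. Of 22 unfolded protein response genes 15 rose and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 6.93e-06, and 0.32 with an estimated correlation). The chaperone gene Hyou1 rose by 0.72 ± 0.10, Herpud1 by 1.13 ± 0.23, Calr by 0.75 ± 0.16 and Pdia6 by 0.68 ± 0.14. None of 22 cholesterol synthesis genes was called, also adjusted over the list alone (camera adjusted p = 0.0652), although 13 were lower with the block (camera adjusted p = 0.00121, and 0.32 with the block and an estimated correlation). The nearest was Sc5d (−0.75, adjusted p = 0.054, and 0.00256 with the block), called as well without vehicle replicate 3 (−0.96) or coiled-coil replicate 1 or 3 (−0.75 each). The list was also called without vehicle replicate 3 (0.00238), full-length replicate 1 (0.0151), or coiled-coil replicate 1 (0.047) or 3 (0.0462), and with the GC and length trend removed (0.0377). Of 35 cell cycle genes 1 was lower, Cenpa (−1.47 ± 0.40), a call lost without full-length replicate 4 (−1.30). None was called adjusted over the list alone and 4 were lower with the block. The camera adjusted p of the cell cycle list was 0.0833 (0.83 with an estimated correlation), and 0.000935 without vehicle replicate 1, 0.0242 without full-length replicate 1 0.00132 without full-length replicate 3 and 0.0273 with the GC and length trend removed.

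Markers of other cells of the mixed glial culture had few calls with full-length NfL without the block and more with it. The mean change of the neuron, astrocyte, oligodendrocyte, fibroblast and border-associated macrophage lists was negative in all 4 batches. The same held for the disease-associated, homeostatic, growth factor, matrix, lysosome, cholesterol synthesis and alternative activation lists, and whether fewer other cells account for part of that was not tested. Neuron markers had a median of −1.15, with 2 of 10 lower and none higher (5 and 0 adjusted over the list alone, 8 and 0 with the block; camera adjusted p = 0.0123, and 0.70 with an estimated correlation). Snap25 averaged 1.69 CPM in vehicle and 0.688 with full-length NfL. Astrocyte markers had a median of −0.73, with 1 of 12 lower, none adjusted over the list alone and 10 with the block (camera adjusted p = 0.0879, and 0.00957 without vehicle replicate 3, 0.046 with the GC and length trend removed and 0.000586 with the block, but 0.28 with the block and an estimated correlation). Oligodendrocyte markers had 1 higher gene of 12, Mag at 0.69, a call lost without vehicle replicate 4 (0.61; 1 and 0 adjusted over the list alone; with the block 2 higher and 5 lower; camera adjusted p = 0.601). No fibroblast or mural marker of 7 was called, also adjusted over the list alone (2 lower with the block; camera adjusted p = 0.287). Pdgfrb, the nearest, was at −1.33 (adjusted p = 0.113, and 0.00842 with the block). Of 5 endothelial markers Cdh5 rose by 1.34 ± 0.34 and Flt1 fell by 1.20 ± 0.33, the second not without vehicle replicate 2 or 4 or full-length replicate 3 (−0.95 to −1.04), over all genes and adjusted over the list alone (camera adjusted p = 0.956). The endothelial median was −0.23 and its mean −0.045, with the camera direction up. Of 10 markers of border-associated macrophages 4 fell and none rose (5 and 2 adjusted over the list alone, 5 and 3 with the block; camera adjusted p = 0.287), F13a1 and Ccl24 among them. S100a8, the only neutrophil or lymphocyte gene tested, averaged 0.455 and 0.392 CPM.

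A further 15 genes called with full-length NfL lost the call in some fits with 1 library fewer, for which the range of the change is in brackets. Casp1 rose by 0.55 ± 0.15, a call lost without full-length replicate 2 or 4 or vehicle replicate 1 (0.47 to 0.51). Erap1 rose by 0.49 ± 0.13, lost without full-length replicate 2 or vehicle replicate 1 or 4 (0.41 to 0.47). Isg20 rose by 1.64 ± 0.47, lost without full-length replicate 2, 3 or 4 or vehicle replicate 1, 2 or 4 (1.45 to 1.68). Naip2 and Oas1g, which have close relatives in the genome, rose by 0.35 ± 0.10 and 0.97 ± 0.28. The first was lost without full-length replicate 3 or vehicle replicate 4 (0.27 and 0.29), the second without full-length replicate 2, 3 or 4 or vehicle replicate 1 or 4 (0.85 to 0.95). Among the falls, Lipa (−0.46 ± 0.12) was lost without vehicle replicate 4 (−0.41), and Rbfox3 (−2.10 ± 0.59) without full-length replicate 4 (−2.01) or vehicle replicate 4 (−1.90). Panx1 (−0.57 ± 0.15) was lost without full-length replicate 2 or 4 or vehicle replicate 1 or 2 (−0.50 to −0.55), and Stab1 (−0.41 ± 0.12) without full-length replicate 2, 3 or 4 or vehicle replicate 2 or 3 (−0.31 to −0.41). Irf4 (−1.18 ± 0.36) was lost without full-length replicate 1, 2 or 4 or vehicle replicate 2, 3 or 4 (−0.99 to −1.21), and Sox9 (−1.38 ± 0.43) without full-length replicate 2, 3 or 4 or vehicle replicate 1, 2 or 4 (−1.07 to −1.51). Cd44 (−0.50 ± 0.16) and Pfkm (−0.35 ± 0.11) were both lost without full-length replicate 2 or 4, vehicle replicate 1, 2 or 4 or coiled-coil replicate 3 or 4 (−0.38 to −0.52 and −0.28 to −0.37). Mrc1 (−0.94 ± 0.31; 805 CPM in vehicle) was lost without any 1 vehicle library, full-length replicate 1, 2 or 4 or coiled-coil replicate 1 (−0.68 to −1.02). Gad1 (−1.21 ± 0.41) kept its call only without full-length replicate 1 or vehicle replicate 3 (−1.03 to −1.28 in the other 10 fits).

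The second comparison asked whether the coiled-coil part of NfL alone acts on microglia. With coiled-coil NfL no gene was called at the threshold by the edgeR test (smallest adjusted p = 0.414). An unadjusted p below 0.05 was found for 1082 genes, 675 of them higher. Of the 35 ways to split the vehicle and coiled-coil libraries into equal groups, 8, the real one included, gave as many, so chance cannot be excluded. DESeq2 called 24 higher and 9 lower genes and limma-voom none. With the block 1 gene was higher, Fcrl5 at 2.81 ± 0.28 (0.388 to 2.90 CPM; adjusted p = 0.00936), and 1 lower, Thbs1 at −0.53 ± 0.06 (adjusted p = 0.0227). DESeq2 with the block called 270 and 249. Coiled-coil replicate 1 decided the count: without it 18 genes were higher and 8 lower, and with the block 383 and 367, a fit chosen after the data were seen. Without all of batch 1 the counts were 4 and 8, and 504 and 528 with the block.

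The genes that full-length NfL changed most had smaller changes with coiled-coil NfL, none of them called by edgeR with all 12 libraries. Selection by the full-length change favours that order. Cd300e averaged 4.09 CPM, a log2 fold change of 2.87 ± 0.60 from vehicle (95% interval 1.5 to 4.24). Ccl5 averaged 182 CPM (2.78 ± 0.62) and Siglece 41.1 CPM (2.16, interval 1.13 to 3.20). Cxcl13 averaged 52.4 CPM against 6.53 in vehicle (3.00 ± 0.63, adjusted p = 0.621), close to the 60.5 CPM with full-length NfL, and was called by DESeq2 and without coiled-coil replicate 1 (3.36). Ebi3 differed by 0.89 ± 0.24 and was called without the same library (1.10). C3 averaged 2064 CPM (1.65 ± 0.41), H2-K1 1752 CPM (0.94 ± 0.25), Irf7 1102 CPM (1.30 ± 0.49) and Cst7 50.8 CPM (1.10 ± 0.32). Nos2 differed by 0.90 (−0.05 to 1.86), Il1b by 0.78 (−0.01 to 1.58) and Tnf by 0.28 (−0.15 to 0.71). Slco2b1 averaged 18.4 CPM (−1.49 ± 0.39), Gpr34 21.3 CPM (−1.03) and Dkk2 19.8 CPM (−1.14). Trem2 averaged 484 CPM (−0.48, interval −0.90 to −0.06) and Apoe 12276 CPM (−0.44, interval −0.76 to −0.11). Tlr2 (−0.02), Tlr4 (−0.02), P2ry12 (−0.08) and Cd14 (−0.01) lay near vehicle, and Tmem119 differed by 0.33 (−0.39 to 1.05).

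Camera called 13 lists with coiled-coil NfL, on medians that were small. Median log2 fold change and adjusted p are given together for each. Placed above other genes were cytokines (0.43, 0.000174), type I interferon genes (0.30, 4.84e-05), antigen presentation (0.31, 0.000497), oxidative phosphorylation (0.14, 1.45e-08) and the unfolded protein response (0.24, 0.00157). The same held for complement (0.19, 0.00942), NF-kB genes (0.18, 0.00364), chemokines (0.19, 0.0331) and NRF2 targets (0.14, 0.0331). Placed below were growth factors (−0.26, 0.00157), homeostatic genes (−0.12, 0.0215), disease-associated genes (−0.11, 0.0331) and neuron markers (−0.36, 0.0298). None of the 13 was called with an estimated correlation (adjusted p = 0.69 to 0.87) or by fry (0.40 or more). The other 15 tested lists had camera adjusted p of 0.0675 or more, of which cholesterol synthesis (0.00376), astrocyte markers (0.00357) and matrix genes (0.0465) were called with the block, but not with the block and an estimated correlation (0.46 to 0.48). Genes called adjusted over the list alone were 5 of oxidative phosphorylation, 3 chemokines, 3 complement genes, 2 NF-kB genes, 1 cytokine gene, and 1 higher and 3 lower homeostatic genes. With the block these counts were larger. They were 11 antigen presentation genes, 10 of interferon, 10 of oxidative phosphorylation, 5 of cytokines, 3 of NF-kB and 2 of the unfolded protein response, all higher. Higher and lower were 8 and 1 chemokines, 8 and 2 complement genes, 5 and 2 toll-like receptors and adaptors, 5 and 5 phagocytic receptors, 4 and 3 efflux genes, 4 and 3 border-associated macrophage markers, 3 and 7 disease-associated genes, 2 and 5 homeostatic genes, 2 and 7 matrix genes, and 2 and 1 alternative activation genes. Only lower were 3 growth factors, 3 oligodendrocyte markers, 2 neuron markers and 2 cholesterol synthesis genes. The cytokine, antigen presentation, oxidative phosphorylation, unfolded protein and growth factor lists kept their calls whichever library was left out. The interferon call was lost without vehicle replicate 1 (0.0561), and the NF-kB (0.117), complement (0.0705) and chemokine (0.24) calls without vehicle replicate 4. The chemokine call was also lost without vehicle replicate 1 (0.0561) or coiled-coil replicates 2 (0.0502) or 3 (0.067). The disease-associated call was lost without vehicle replicates 1 (0.137) or 3 (0.222) or coiled-coil replicates 2 (0.0701), 3 (0.144) or 4 (0.116), and the homeostatic call without vehicle replicate 3 (0.166) or coiled-coil replicate 4 (0.0557). The NRF2 call was lost without coiled-coil replicates 1 (0.409) or 4 (0.0557) or vehicle replicates 2 to 4 (0.173 to 0.309). The neuron marker call was lost without coiled-coil replicate 3 (0.555) or vehicle replicates 1 (0.0546), 2 (0.145) or 4 (0.24). Some lists without a call in the full set gained one on leaving out a library. Cell cycle did so without coiled-coil replicates 1 (0.0327) or 2 (0.00787) or vehicle replicate 4 (0.0243). Glycolysis did so without vehicle replicate 1 (0.00125), coiled-coil replicate 3 (0.02) or full-length replicate 3 (0.0443). Cholesterol synthesis did so without coiled-coil replicate 1 (0.00519) or vehicle replicate 3 (0.000668), and astrocyte markers without vehicle replicate 3 (0.00593). The mean of the phagocytic list was 0.03, with its median at −0.06 and camera down, and that of the efflux list 0.09, with its median at −0.02 and camera up. Endothelial markers were down in camera and up in fry.

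**Figure D3:**
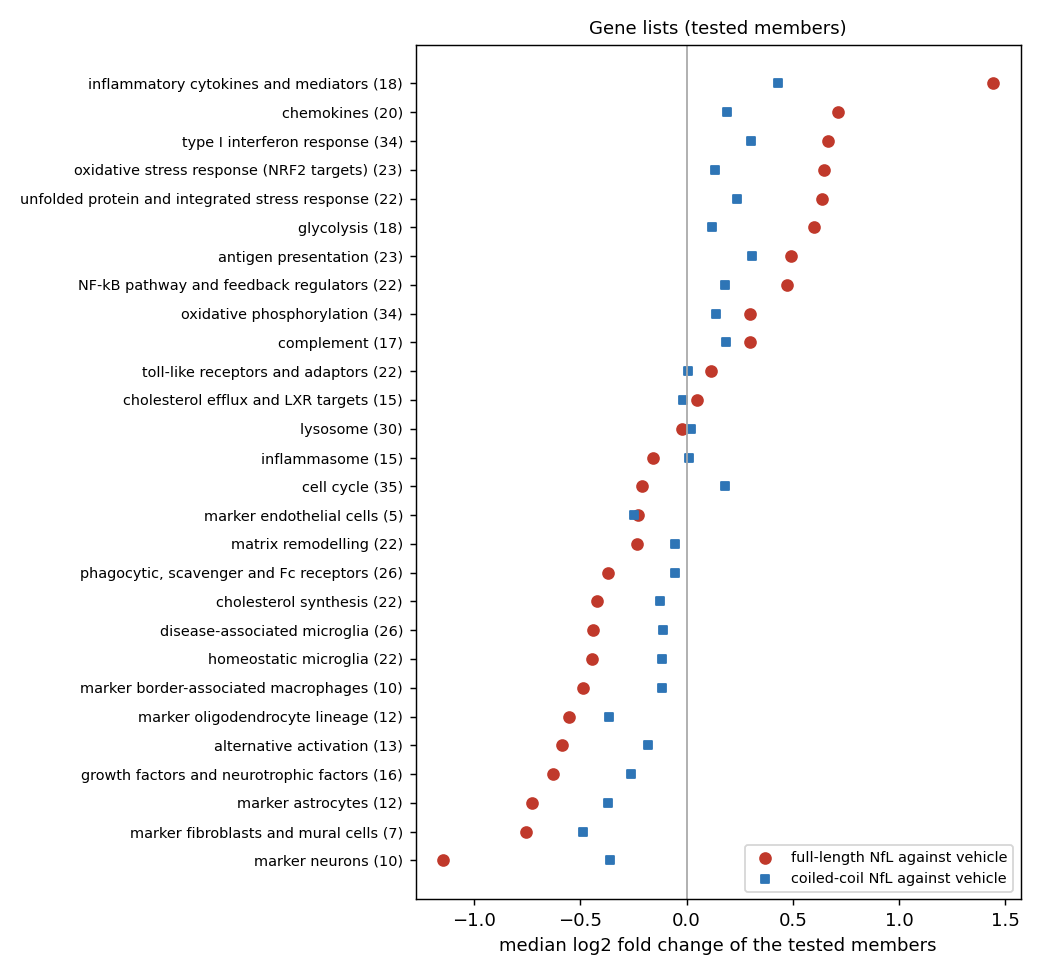
Median log2 fold change from vehicle of the genes of each list, with circles for full-length NfL and squares for coiled-coil NfL (n = 4 libraries per group). The cytokine list lies at 1.44 with full-length and 0.43 with coiled-coil NfL, and the neuron markers at −1.15 and −0.36.

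The third comparison set the 2 forms against each other at the same dose. Full-length NfL left 202 genes higher and 197 lower than coiled-coil NfL. With batches 2 and 4 summed the counts were 0 and 1, from 3 libraries per group. That fit was chosen after the data were seen, because same-group libraries of these batches were nearly alike (mean chi-square per gene 10.5 to 12.6, against 23.8 to 113 for other pairs of a group). Sez6l2 (ENSMUSG00000030683, chromosome 7, 126950563 to 126970606), known from neurons, averaged 16.2 CPM with full-length and 2.92 with coiled-coil NfL, against 2.94 in vehicle (log2 fold change 2.46 ± 0.34 between the forms, adjusted p = 0.00887). Rims3 (ENSMUSG00000032890, chromosome 4, 120854816 to 120896579), a gene of synaptic release, averaged 25.4 and 5.05 CPM (2.33 ± 0.31, adjusted p = 0.00835). Both kept their calls whichever library was left out. Slco2b1 was lower with the full-length form (−2.80 ± 0.43, adjusted p = 0.0121), as was Trem2 (−1.14 ± 0.19, adjusted p = 0.0139), and on leaving out single libraries both calls were lost without full-length replicate 2 (−2.62 and −1.01) or 4 (−2.85 and −1.06).

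Other genes with a call between the forms rested on more libraries. Nos2 was higher with full-length NfL (2.12 ± 0.40, adjusted p = 0.0240), as were Cd300e (2.35 ± 0.51), Siglece (1.98 ± 0.44) and Adgrg6 (2.08 ± 0.48). Dkk2 (−2.52 ± 0.49), Gpr34 (−2.28 ± 0.51), Cytip (−2.12 ± 0.45) and Samd4 (−1.99 ± 0.37) were lower. Each of these 8 lost its call without full-length replicate 2, full-length replicate 4 or coiled-coil replicate 1, and all but Dkk2 without coiled-coil replicate 3. Cd300e was then at 2.05 or more, Nos2 at 1.95 or more, Siglece at 1.70 or more and Adgrg6 at 1.96 or more, and Dkk2 (−1.98), Gpr34 (−1.89), Cytip (−1.56) and Samd4 (−1.71) reached these values nearest to 0. Apoe had a change of −0.54 ± 0.14 (adjusted p = 0.0648, and 0.0204 with the block). Tnf differed by 0.56 ± 0.19 (adjusted p = 0.120) and was called with the block (0.0163) and without full-length replicate 3 (0.72). Cd14 differed by −0.43 (adjusted p = 0.365) and was called with the block (0.0106). Il1b (0.67 ± 0.35), Tmem119 (0.39), Tlr4 (−0.13), P2ry12 (−0.08) and Tlr2 (−0.01) were not called. The block gave 1321 higher and 1485 lower genes, DESeq2 797 and 628, and a fit of only these groups 85 and 83. The counts fell to 14 and 18 without full-length replicate 2, 15 and 22 without full-length replicate 4, 35 and 55 without coiled-coil replicate 1, 31 and 59 without coiled-coil replicate 3 and 75 and 94 without coiled-coil replicate 4. They were 113 and 102 without vehicle replicate 2, and 137 and 112 without vehicle replicate 4. Leaving out full-length replicate 1 gave 324 higher genes, and leaving out coiled-coil replicate 2 gave 306.

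Camera called 11 lists between the forms. With median and adjusted p in that order, higher with full-length NfL were cytokines (0.72, 3.55e-05), NF-kB genes (0.24, 0.0076), interferon genes (0.41, 0.0007), glycolysis (0.44, 1.05e-05), oxidative phosphorylation (0.17, 3.46e-06), NRF2 targets (0.45, 3.29e-05) and the unfolded protein response (0.48, 1.04e-05). Lower were disease-associated genes (−0.30, 2.18e-05), homeostatic genes (−0.26, 0.00624), growth factors (−0.44, 0.0038) and cell cycle genes (−0.47, 0.000624). With an estimated correlation the adjusted p was 0.35 to 0.75 for all 11. By fry the disease-associated, homeostatic and glycolysis lists were called (0.0168) and the unfolded protein list (0.046). Single genes called numbered 4 of 18 in glycolysis (11 higher and 1 lower adjusted over the list alone), 4 of 26 disease-associated genes (11 lower and 1 higher adjusted over the list alone), 4 of 22 homeostatic genes (8 adjusted over the list alone), 3 of 16 growth factors (4 adjusted over the list alone) and 1 of 18 cytokine genes (7 adjusted over the list alone). With the block 11 glycolysis genes were higher, 13 disease-associated and 9 homeostatic genes lower, 8 cytokine genes higher and 14 unfolded protein genes higher. The interferon call was lost without coiled-coil replicate 1 (0.131) and the cell cycle call without full-length replicate 2 (0.0747). The other 17 lists had adjusted p of 0.0638 or more, of which neuron markers came under the threshold without vehicle replicate 3 (0.0299), coiled-coil replicate 3 (0.00268) and full-length replicates 2 (0.0461) and 4 (0.0263), and with the block (0.00338). Cholesterol synthesis (0.00271) and astrocyte markers (0.00923) did so without coiled-coil replicate 3, cholesterol synthesis also without full-length replicate 1 (0.0272) and with the block (0.00316), astrocyte markers with the block (0.00463), and border-associated macrophage markers without coiled-coil replicate 1 (0.0446). The 3 lists that gained a call with the block had none with the block and an estimated correlation (0.30 to 0.42). Antigen presentation genes had a median of 0.18 and a mean of −0.02, complement genes −0.02 and 0.13 with camera up, and efflux genes 0.00 and 0.03 with camera down.

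The estimated changes of the forms mostly had the same sign, although edgeR called no gene with coiled-coil NfL in the fit of all libraries without the block. Across the 14687 genes, which are not independent replicates, the log2 fold changes of the forms correlated at r = 0.787, and 80.9% had the same sign. With all 3 groups drawn around the same means, simulated unchanged groups gave r = 0.498 and 66.7% of equal sign from the shared vehicle group alone. These groups were drawn without the batch pairing that the real libraries have. The covariance of the differences in log2 CPM was 0.146, against 0.0438 in that simulation. With no library shared, r was 0.531 on average, from 0.165 to 0.686 over 6 ways to split the batches, and with the vehicle libraries divided between the forms it was 0.429. Of the 2062 genes higher with full-length NfL, 2032 had a positive change with coiled-coil NfL, with a median ratio of 0.387, and of the 1594 lower genes 1565 had a negative change, with a median ratio of 0.345. These shares include the pull of the shared vehicle libraries. The genes were selected by their full-length result, which favours a lower ratio. The ratios also average unlike batches. Slopes of the coiled-coil difference on the full-length response of the other batches were −0.00144, 0.668, 0.160 and 0.627 in batches 1 to 4. With coiled-coil replicate 1 left out and the block, 737 of 749 genes called with coiled-coil NfL had the same sign with full-length NfL. Of these 749, 703 were called in that direction with full-length NfL and the block, and 573 without the block. Independent lists would share 82.3 higher and 81.9 lower genes, where 350 and 353 were shared, a value that makes no allowance for the vehicle libraries both effects use.

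**Figure D4:**
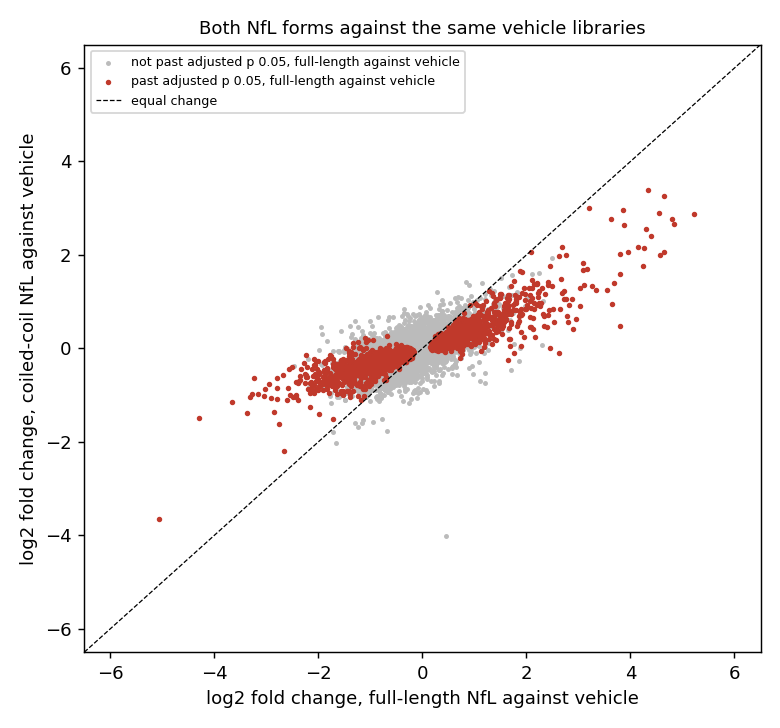
Log2 fold change from vehicle of each of 14687 genes with full-length NfL (horizontal) and coiled-coil NfL (vertical), with genes past an adjusted p of 0.05 for full-length NfL in red and the line of equal change dashed. Most red points lie nearer to 0 on the vertical axis, with a median ratio of 0.387 for higher and 0.345 for lower genes. The red genes were selected by their full-length result, which favours a lower ratio.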

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

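The comparisons of batch 1 with the other batches were chosen only after the result was seen. A library was singled out where its gap to the nearest library of its group took up nearly all of the range of the 4 libraries. Of 477 groups of 4 libraries 44 passed this limit (9.22%), where chance gives about 1 in 20. Coiled-coil replicate 1 accounted for 11, full-length replicate 1 and vehicle replicate 1 for 8 each, and vehicle replicate 3 for 7.

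Coiled-coil replicate 1 lay apart from the other coiled-coil libraries mostly in genes called with full-length NfL. The search covered library measures, gene lists and named genes only. Of the 112 genes named for full-length NfL 104 were called with it, so most outlying genes were bound to be such genes. Trem2 was at 646 CPM there against 417 to 441 in the others, Ank at 134 against 78.0 to 87.1, Adamts1 at 68.4 against 33.3 to 34.4, Cytip at 25.9 against 8.03 to 9.79 and Mamdc2 at 18.8 against 1.81 to 2.73. Ikbke was at 142 against 229 to 243, Herpud1 at 26.2 against 47.8 to 51.9, and Bin1 at 119 against 142 to 146. Clec12a was at 425 against 534 to 542 and S100a8 at 1.11 against 0.065 to 0.115, and neither was called with full-length NfL. Its 10 most abundant genes took 14.6% of the counts, against 11.1% to 11.5% in the others.

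In vehicle replicate 1 Slc13a3 was at 358 CPM against 28.2 to 30.0 in the other vehicle libraries, Siglece at 18.6 against 5.24 to 7.19, Cd55 at 0.998 against 0.126 to 0.201 and Adgrg6 at 4.64 against 0.648 to 1.05, all nearer to the full-length libraries. Cd14 was at 1700 against 833 to 934, Cd44 at 468 against 346 to 358, both away from the full-length libraries, and Pdgfb at 45.4 against 70.5 to 72.5. The mean log2 CPM of NRF2 targets was 6.64 there against 5.77 to 5.91.

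In full-length replicate 1 Cytip was at 5.57 CPM against 2.05 to 2.32 in the other full-length libraries, Mamdc2 at 3.8 against 0.474 to 0.628, Snap25 at 1.26 against 0.46 to 0.563 and S100a8 at 1.22 against 0.0402 to 0.209. Fth1 was at 11900 against 9850 to 10200, Txn1 at 185 against 141 to 148, Casp1 at 114 against 174 to 180 and Oas1g at 50.1 against 69.3 to 71.4. Ldha was at 243 in full-length replicate 2 against 219 to 221.

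Batch 3 stood apart in P2ry12, at 64.2 CPM in vehicle replicate 3 (others 30.6 to 36.2), 56.7 in full-length replicate 3 (29.9 to 33.7) and 59.7 in coiled-coil replicate 3 (32.6 to 33.7). The mean log2 CPM of astrocyte markers was −0.724 in full-length replicate 3 (others 0.897 to 1.11) and −0.254 in coiled-coil replicate 3 (1.3 to 1.53). In vehicle replicate 3 Mrc1 was at 1190 against 649 to 730, Calr at 1040 against 626 to 679, Pdia6 at 228 against 144 to 158, Pros1 at 205 against 158 to 164 and Hexa at 1990 against 1610 to 1620, and the mean log2 CPM of growth factors was 3.93 against 4.33 to 4.36. Hexa was at 1700 in coiled-coil replicate 3 against 1590, where the mean log2 CPM of inflammasome genes was 5.57 against 5.36 to 5.39, and Cst7 at 87.0 in full-length replicate 3 against 56.2 to 61.3. In vehicle replicate 4 mitochondrial genes held 0.518% against 0.400% to 0.419%, and Vegfb was at 32.2 CPM against 27.0 to 27.5.

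Coiled-coil replicate 1 had almost none of the response of its group. Across genes, its difference from vehicle replicate 1 had a slope of 0.0199 on the mean coiled-coil response of the other batches. On their mean full-length response the slope was −0.00144. The 95% interval of the first slope, −0.0035 to 0.0443, came from resampling genes, so it does not hold the spread between wells. An exchange of labels with vehicle replicate 1 would need a slope near −1 if the coiled-coil well had responded as in the other batches. The slope argues against that case only, because a well with almost no response would give a slope near 0 with either label. Coiled-coil replicate 3 had a partial response, with slopes of 0.314 on the other coiled-coil batches and 0.160 on the full-length response, against 0.958 and 0.668 in batch 2 and 1.06 and 0.627 in batch 4. The group response thus came mostly from batches 2 and 4. Replicate 1 of coiled-coil NfL and of vehicle were the closest of all library pairs (mean chi-square per gene 8.75). Cells of batch 1 that answer less to any NfL would lower both forms alike. The full-length slope of batch 1 was 0.543, the lowest, against 1.16, 0.668 and 1.12 in batches 2 to 4. A weaker answer in batch 1 may thus be part of the pattern, but the 2 forms were not lowered in proportion. A well that received little or no coiled-coil NfL is a candidate explanation that the slopes leave open, as is a vehicle well that received some NfL. For the latter the genes of vehicle replicate 1 went both ways. Slc13a3 was high, and Slco2b1 (15.7 CPM against 39.3 to 77.8 in the other vehicle libraries), Trem2 (626 against 687 to 705) and Pdgfb were low, all toward the full-length libraries. Dkk2 was not low (46.9 against 24.8 to 53.6), and Cd14 and Cd44 were high. These values also hold the difference between batches. Trem2 in coiled-coil replicate 1 lay with vehicle (677 ± 34.5 CPM), and a threshold in the response to the coiled-coil form, the biological alternative, was not tested.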

How the results depend on the processing

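The removal of a GC and length trend, the fit without batch 1 and without a block, the fit without coiled-coil replicate 1 with the block, the sum of batches 2 and 4 and the split of the batches between the forms were chosen only after the data were seen. DESeq2 size factors, upper-quartile factors and both filters on low counts left the 6 gene counts within 1.5 times their main values. Upper-quartile factors turned the full-length balance to 1691 higher and 2003 lower with no called gene of the opposite sign, and trend removal gave 30 called genes the opposite sign. Full-length NfL against vehicle (2062 higher, 1594 lower) gave 3148 and 3284 genes with the block, 3142 lower with the block in DESeq2, 3132 lower without batch 1 and 2931 lower without batch 3 with the block, and 3243 and 3265 without coiled-coil replicate 1 with the block. Trend removal gave 1022 lower genes, and 4312 and 2577 with the block. Batches 2 and 4 summed gave 616 and 424, an adjusted p of 0.01 gave 919 and 628, and a 2-fold change 308 and 435, fewer by construction. Leaving out 1 library gave 1392 to 2349 higher and 992 to 1735 lower genes. For coiled-coil NfL against vehicle (0 by edgeR, 1082 at an unadjusted p under 0.05, 0 by limma-voom) DESeq2 gave 24 and 9, the block 1 and 1, trend removal with the block 1 and 1, DESeq2 with the block 270 and 249, the fit without batch 1 4 and 8, and 504 and 528 with the block, and the fit without coiled-coil replicate 1 with the block 383 and 367. Leaving out 1 library gave 0 to 18 and 0 to 8, both highest without coiled-coil replicate 1. For full-length against coiled-coil NfL (202 and 197) DESeq2 gave 797 and 628, the block 1321 and 1485, DESeq2 with the block 1381 and 1515, and only these groups 85 and 83. Without batches 1 to 4 in turn, with the block, the counts were 793 and 1049, 671 and 844, 702 and 799, and 458 and 626. Without batch 1 and no block 79 were higher, without coiled-coil replicate 1 with the block 611 and 653, and with batches 2 and 4 summed 0 and 1, in fits with fewer libraries. Trend removal gave 111 lower genes, and 2470 and 1067 with the block. An adjusted p of 0.01 gave 9 and 18 and a 2-fold change 35 and 57. Leaving out 1 library gave 14 to 324 higher genes, lowest without full-length replicate 2, and 18 to 277 lower genes. Where these counts moved and neither fewer libraries nor a stricter threshold shows why, the cause was not tested.

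Camera called 12, 13 and 11 lists in the 3 comparisons. With an estimated correlation it called 0 in each, with and without the block. Fry called 9, 0 and 4, and with the block 21, 0 and 15. Between the forms 17 lists were called without coiled-coil replicate 1 with the block, and 17 with the trend removed with the block. Leaving out 1 library gave 11 to 16, 9 to 14 and 11 to 14 lists. The first principal component held 44.1% with 5000 genes. The correlation of the forms was 0.429 with the vehicle libraries divided, 0.531 with no shared library, 0.914 over called genes only, and 0.679 to 0.840 on leaving out 1 library. The first 2 have fewer libraries per effect. Of the values of named genes, the block left 164 with the same call and gave 7 a call, and DESeq2 left 155 and gave 7 a call. Leaving out single libraries left 1909 calls as they were, ended 136 and added 7. Of the 104 named genes called with full-length NfL 84 kept the call whichever library was left out, and of 12 between the forms 2 did. The block changed no call of a named gene or list other than those printed beside the results. Genes under about 1 CPM, such as Pdgfrb, Rbfox3 and S100a8, had too few counts for firm values.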

Other observations

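The tests on symbol families, on batches, on other splits of the samples, on shared libraries and on a bacterial component were chosen only after the result was seen. The removal of the GC and length trend was also chosen after the data were seen. Only the limits for reading its result, set for the fit with the block, were written down before that result. With full-length NfL, several families of gene symbols held more higher genes than the rest. Fisher's exact test, used here, takes genes as independent, but genes of a family can move together. Its p-values therefore do not measure the spread between libraries. Among genes grouped by the start of their symbol (149 families of at least 10, 298 tests by Fisher's exact test with Benjamini-Hochberg adjustment, 12 past 0.05), 29 of 49 Mrpl genes of the mitochondrial ribosome were higher (59.2% against 15.1% of other genes, adjusted p = 3.27e-10), Mrpl45 by 0.94 and Mrpl42 by 0.79. So were 17 of 28 Mrps genes (adjusted p = 3.71e-06), 12 of 14 Psmd genes of the proteasome cap (adjusted p = 1.05e-06), Psmd14 by 0.90, and 9 of 12 Psmb genes of its core (adjusted p = 0.000245), Psmb2 by 0.74. Translation factors (24 of 60 Eif genes, Eif4g2 by 0.78), cytochrome oxidase genes (12 of 24 Cox genes, Cox6a1 by 0.60) and nucleoporins (9 of 18 Nup genes, Nup62 by 0.63) had adjusted p of 0.00015, 0.00232 and 0.0158. The 49 Rpl genes of the cytoplasmic ribosome, with low counts here, held no call by edgeR in either direction (adjusted p = 0.0143 for higher and 0.0649 for lower genes). Of the 45 Rps genes 4 were higher (8.89% against 15.3%, adjusted p = 0.839). The results for higher genes, Rps aside, stayed past 0.05 with the GC and length trend removed, whereas 11 of 14 Ndufa genes (adjusted p = 1.43e-05) did not (0.404). Of 334 Zfp zinc-finger genes, 10 were higher (2.99% against 15.6%, adjusted p = 5.88e-11) and 68 lower (20.4% against 11.6%, adjusted p = 0.000245, and 0.158 with the trend removed), Zfp395 by −0.99. Of 27 Klhl genes 10 were lower (adjusted p = 0.0168, and 0.495 with the trend removed), Klhl23 by −1.61.

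Batches differed in 3550 genes (24.2% of those tested). Pdgfra, a marker of oligodendrocyte precursors, spanned 5.34 on the log2 scale between batches, with batch 3 lowest. Wide spans were also measured for Hp (4.33, highest in batch 1), Vxn (3.88), Cntn1 (3.80), H2-Q6 (3.58, lowest in batch 1) and Ccl8 (3.24, highest in batch 3). Oligodendrocyte markers spanned 1.95, astrocyte markers 1.83 (batch 3 at −1.28), fibroblast markers 1.61 and neuron markers 1.35. Type I interferon genes spanned 1.08, lowest in batch 1 (−0.648), and cell cycle genes 1.04, highest in batch 3 (0.617). Oxidative phosphorylation genes spanned 0.109.

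The full-length response was large against other groupings of the same libraries. Of the 35 splits of the 8 libraries 1, the real one, called 3656 genes and the highest other split called 1 (5653 and 3896 at an unadjusted p under 0.05), so chance is excluded over splits that take the 8 libraries as separate and unpaired. Same-group libraries of batches 2 and 4 were nearly alike (mean chi-square per gene 10.5 to 12.6, against 23.8 to 113 for other pairs of a group), and with them summed 616 higher and 424 lower genes were called. The 8 splits that part all 4 batches, as the pairing asks, are too few for a share under 0.05 (6432 genes with the block in the real one and 1 in the highest other). GC content and gene length cannot be the whole cause, since 83.8% of the blocked calls were kept with their trend removed (75.6% without the block), although log2 fold changes correlated with log length at −0.168 across genes. An effect of full-length NfL, or of anything else in its preparation, may account for the rest.

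For coiled-coil NfL against vehicle the real split called 0 genes by edgeR, so all 35 splits were bound to call as many and that count says nothing. At an unadjusted p under 0.05 the real split had 1082 genes, 8 of 35 splits had as many and the highest other had 3847, so chance cannot be excluded. The split with the most calls set vehicle replicates 1, 2 and 4 with coiled-coil replicate 1 against the rest and called 960, which points to a structure of the samples. For full-length against coiled-coil NfL 1 of 35 splits, the real one, called 399 genes and the highest other 0 (3175 and 2740 at an unadjusted p under 0.05). With batches 2 and 4 summed 1 gene was called, so chance is excluded only over splits that take these libraries as separate and unpaired. The 8 splits that part all batches are again too few, with 2 and 2806 genes in the real splits with the block and 0 in the highest other of each.

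The effects of the forms correlated across genes at 0.787. With no library shared the correlation averaged 0.531, lowest (0.165) where the coiled-coil effect came from batches 1 and 3. Most of these ways set the nearly alike batches 2 and 4 on opposite sides, which keeps part of the sharing. With batches 2 and 4 on the same side the correlation was 0.686 and 0.165. Both values are positive, so the shared vehicle libraries are unlikely to be the whole cause, but the values differ widely. Tnf, Il1b and Nos2, 3 of 5 tested genes that bacterial endotoxin raises, were higher with full-length NfL, while Cd14 and Tlr2 were not. A bacterial component in both preparations therefore remains a possible explanation that these values cannot separate from a shared action of the NfL forms, as no protein without NfL was added as a control in these 12 libraries.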
